A study of Canis lupus familiaris with 24 samples.

How the data were processed

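Gene expression was measured in pieces of lung from 3 mongrel dogs, with 1 array per piece and 24 arrays in all. Per the labels, the left lung of each dog was lavaged with saline, 20 ml/kg on 4 occasions, a mild injury that washes surfactant out of the alveoli, and the right lung served as the control. The lungs were ventilated separately for 5 h at 25 breaths/min, and only the control lung received 5 cmH2O of positive end-expiratory pressure (PEEP). Lavage, side and PEEP therefore differed together between the lungs, and "injured" stands for all 3. Each array belongs to 1 of 8 groups, made of the lung, the level (apex or base) and the position (dependent, the lower part under gravity, or nondependent), and each group has 3 arrays, 1 per dog. The labels mention a further site, the middle of the base, which was not analysed here.

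RNA of the dog was hybridised to a human array, part A of the Affymetrix Human Genome U133 set, per the file headers. The deposited values are a signal intensity per probe set on a linear scale, a detection call and a detection p-value for each array. On each array the 2% trimmed mean of the deposited signal was 149.94 or 149.95, so the authors' values had been scaled to about 150, and the software, its settings and any masking of probes are not given in the sources used here. The deposited detection p-values are a measure within one array and compare no samples. From the values they took, the number of probe pairs behind a probe set was estimated for 98.65% of probe sets as some number up to 11. The median was 7 pairs, with under 5 pairs for 9.19% of them. The estimate assumes how finely p-values are spaced for a given number of pairs. This was not checked against the software, so the counts may be too high. A human probe set thus rests on fewer probes than its design, and probes that match the dog sequence poorly lower the signal, so levels of different genes were not compared. The deposited table of values for the whole series held the same intensities as the arrays' own files, with a largest difference of 0. The files recorded no scan day, chip lot or other batch. No 2 arrays were identical.

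The 22283 probe sets included 68 control probe sets and 11 with no call on any array, all left out. The remaining ones were tested when called Present on at least 6 of the 24 arrays, which left 20034. Signals were scaled to the same trimmed mean and put on the log2 scale with no offset, and the 3 signals of 0 among them were set to 0.1. Gene names came from the platform's annotation. Of the tested probe sets, 17255 had 1 gene symbol, 930 had several and 1849 had none, and no gene was named from a probe set with several. They covered 11226 symbols, of which 10055 (89.57%) were also symbols in the RefSeq gene table of the dog assembly UU_Cfam_GSD_1.0.

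Differences were tested with limma 3.58.1 in R 4.3.3. All 24 arrays entered 1 linear model with the 8 groups and the dog as a block, followed by empirical Bayes moderation with an intensity trend and Benjamini-Hochberg adjustment over the 20034 probe sets at 0.05. The dog was a block because the 8 pieces of a dog come from the same animal per the labels. The pairing also showed in the data: the deviations of arrays from their group means had a median correlation of 0.236 within a dog (lowest 0.007) and -0.136 between dogs, and the nearest array by deviation was of the same dog for 24 of 24 arrays. The correlation of pieces from the same lung of a dog, beyond the dog itself, was estimated at -0.0396 and was set to 0. The comparisons were injured minus control lung as the mean of 4 sites and at each site, the interactions of injury with position and with level, and the dependent against nondependent and base against apex contrasts within each lung. With that correlation at 0 the model takes the pieces of a lung as separate units, although the lavage was given to whole lungs, and only the alternative on per-dog means has the 3 dogs as its units. The number of arrays limits the precision: the median SE was 0.18 (log2) for the mean of 4 sites and 0.36 for a single site.

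The comparisons, the tests, the alternatives, 25 gene lists and the rule for naming genes were fixed before the data were examined. For the mean of 4 sites, the rule takes the 12 largest increases and the 10 largest decreases among probe sets with an adjusted p under 0.05, 1 gene symbol and the same sign in 3 dogs, using each gene's brightest tested probe set. For every other comparison it takes up to 5 in each direction, or up to 5 by smallest p, with values alone, where fewer than 5 passed. From each list it takes up to 4 members that passed, or the 2 with the smallest p where fewer than 2 passed, and outside the mean of 4 sites only from lists that passed. A fixed set of genes of inflammation, clotting and surfactant could be named throughout, of which CCL2, F3 and AQP5 had no tested probe set of their own. Where a gene named as passing has further tested probe sets with another sign, this is said beside it. A gene called Present on no array of a side has only a bound on its change: the other side's mean against, per array, the higher of its own signal and the lowest signal called Present. This bound covers detection alone and not the spread between dogs.

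The lists cover inflammatory cytokines and chemokines, NF-kB feedback and endothelial adhesion, IL-6/STAT3 and acute phase, immediate early and stretch-responsive genes, coagulation and fibrinolysis, hypoxia and glycolysis, oxidative stress and metallothionein, heat shock and unfolded protein response, interferon response, extracellular matrix and remodelling, fluid transport, cholesterol and fatty acid synthesis, and the cell cycle. Further lists hold markers of neutrophils, macrophages and monocytes, T and NK cells, B and plasma cells, alveolar type 2 and type 1 cells, airway epithelium, endothelium, smooth muscle and fibroblasts, red cells and platelets, pleural mesothelium, and airway cartilage and glands. Each list was tested against the other genes with cameraPR of limma, with a preset correlation between genes of 0.01 and again with a correlation estimated from the residuals of each list, adjusted over the 25 lists of a comparison.

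The alternatives were quantile normalization, median centring, no detection filter and filters of 3 and 12 Present arrays, an offset of 50, no replicate block, array quality weights, per-dog means paired by dog, each dog left out in turn, an adjusted p under 0.10 and, for lists, the mean of a gene's probe sets. Per-dog means were not run at single sites. An analysis without the 3 arrays of dog 3 that stood apart and one of the oxidative stress list without its metallothioneins were added after seeing the data, as was a model with each array's 3' minus 5' log2 signals of GAPDH and ACTB as covariates. The procedure was tested on simulated data of 20034 probe sets, with 100 changed at each of 2 sizes. For the mean of 4 sites it recovered 70 of 100 changes of log2 1 and 96 of 100 of log2 2, with 9 of 19834 unchanged probe sets called. For the base nondependent site it recovered 10 of 100 and 73 of 100, with 2 unchanged probe sets called. For that site minus the mean of the other 3 it recovered 12 of 100 and 61 of 100. A list shifted by 0.5 was called with 0 of the other lists. The simulated noise was normal and independent between genes and arrays, without shared deviations of a lung or outlying arrays. These rates therefore hold for such noise, and whether they hold for the real arrays was not tested. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.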

Results

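The arrays profiled 24 pieces of dog lung taken after 5 h of ventilation, from the apex and base and the dependent and nondependent parts of a lavage-injured lung and of the control lung of the same 3 dogs. Each of the 8 groups held 3 arrays, 1 per dog. Between 60.78 and 82.32% of probe sets were called Present on an array, with 60.78 to 67.59% in dog 1. Arrays of a group had a median correlation of 0.806. Principal components 1 and 2 held 16.78 and 10.66% of the variance. The injured-lung arrays of dog 3 from the apex dependent, apex nondependent and base dependent sites stood apart from the others: their highest signals were 27749, 22155 and 26350, against at most 20465 on any other array. These 3 arrays were all of 1 lung of 1 dog.

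The first comparison asked which genes differed between the injured and the control lung over the 4 sites together. HAS2, which makes hyaluronan, rose 3.08-fold (log2 change 1.62 ± 0.33, SE, 12 arrays per lung from 3 dogs, limma adjusted p = 0.0434), and VCAN, the matrix proteoglycan versican, rose 2.02-fold (1.01 ± 0.16, adjusted p = 0.00703). The metallothioneins MT2A (1.45 ± 0.22, adjusted p = 0.00703), MT1F (1.27 ± 0.20) and MT1H (1.14 ± 0.21), small proteins that bind zinc and copper, rose together. Among the decreases, SEC14L3, a lipid-binding protein, fell by 1.67 ± 0.34 (adjusted p = 0.0395), and RAMP2, a partner of the adrenomedullin receptor in endothelium, fell by 0.98 ± 0.20. In all, limma called 42 of 20034 probe sets, 27 higher and 15 lower in the injured lung, and each had the same sign in 3 dogs. These tests took the pieces of a lung as separate units. On per-dog means limma called 6 probe sets, 5 of them among the 42. Of all results of named genes run on per-dog means, 4 stayed past the threshold and 23 did not.

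The RNA-binding protein HNRNPAB rose from a mean log2 signal of 7.46 ± 0.20 (SD, n = 3 dogs) to 8.78 ± 0.57, with a limma adjusted p of 0.00703. PRMT1, an arginine methyltransferase, rose by 1.21 ± 0.19, the stress granule protein G3BP1 by 1.08 ± 0.20, and TRIB1, a pseudokinase, by 1.00 ± 0.18. CCT8, a subunit of the cytosolic chaperonin, rose by 1.21 ± 0.23, although it was called Present on 7 of 12 arrays of either lung and its other probe set changed by 0.10. NAMPT, an enzyme of NAD synthesis that is also secreted as a cytokine, rose by 1.38 ± 0.29 (adjusted p = 0.049), while its other probe set stood at -0.05. PWP1 rose by 1.09 ± 0.21.

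Further decreases included HSPB2, a small heat shock protein (-1.52 ± 0.29, SE), DCXR, a carbonyl reductase (-1.48 ± 0.30), and PTPRF, a receptor tyrosine phosphatase (-1.14 ± 0.20). SEC14L3, HSPB2 and DCXR were called Present on 8, 5 and 5 of the 12 injured-lung arrays and on 12, 8 and 11 of the control arrays. SRGAP3, a GTPase-activating protein (-1.44 ± 0.21), and PLCB4, a phospholipase C (-1.15 ± 0.22), fell, with other probe sets at 0.04 and 0.44. SMAD6, an inhibitor of BMP signalling (-0.85 ± 0.15), had 1 of 3 further probe sets with the same sign, and PTPRF had 2 of 3. The transcription factor KLF4 fell by 0.76 ± 0.15, and its other probe set stood at -0.70. CAMK2N1, an inhibitor of CaM kinase II, fell by 0.71 ± 0.14. SEC14L3 was also lower by a log2 difference of -2.57 in the 3 outlying arrays of dog 3 than on the other 5 arrays of that dog. Those 5 are the dog's control-lung arrays and its injured base nondependent array. The difference between the lungs therefore enters this and every later comparison within dog 3.

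With no replicate block limma called 6 probe sets in place of 42, and 6 when the pieces of a lung were averaged per dog and paired by dog. With the 3' minus 5' signals of GAPDH and ACTB, taken as a measure of RNA quality, as covariates, HAS2 stood at 1.34 (adjusted p = 0.0945), MT2A at 1.29 (adjusted p = 0.0224), and the adjusted p of the cytokine and NF-kB lists given next was 0.124 and 0.0741. These control probe sets are of human sequence, so their match to the dog may also enter the measure. That of ACTB was below 0 on most arrays, down to -1.81. Limma called 3 without dog 1, 26 without dog 3 and 0 without dog 2, where 1502 had an unadjusted p under 0.05.

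None of 22 tested inflammatory cytokines and chemokines passed, over all genes or adjusted over the list alone, although 19 were higher in the injured lung and the list test passed (adjusted p = 0.0437, and adjusted p = 0.103 with an estimated correlation). Its members with the smallest p were CCL4, a macrophage chemokine (log2 change 0.67), and IL1RN, the interleukin-1 receptor antagonist (0.39). The list of NF-kB feedback and endothelial adhesion was similar, with 15 of 19 higher and 0 passing (adjusted p = 0.0443, and adjusted p = 0.132 with an estimated correlation), led by the adhesion molecules SELE (0.72) and VCAM1 (0.40). Without the 3 outlying arrays of dog 3 the adjusted p was 0.155 for either list, and within dog 3 the medians of the lists were 0.35 and 0.26 higher on those arrays than on the other 5. The cytokine genes IL6 (-0.04), CXCL8 (0.42), IL1B (0.07) and TNF (0.00), the prostaglandin synthase PTGS2 (-0.11) and the urokinase receptor PLAUR (-0.18) did not pass.

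Oxidative stress and metallothionein genes rose as a list (limma cameraPR adjusted p = 4.86e-07, and adjusted p = 0.00398 with an estimated correlation). Of 21 tested members 4 rose by their brightest probe set, each a metallothionein (MT2A, MT1F, MT1H and MT1G at 0.94, whose other probe set stood at -0.04), 0 fell, and 7 rose adjusted over the list alone. A dimmer probe set of MT1X also passed (1.12, limma adjusted p = 0.00703). The dog gene table names 2 genes as metallothionein 1 or 2, and which dog transcripts these human probe sets match was not analysed here. Without the metallothioneins the list had an adjusted p of 0.707. On the outlying arrays of dog 3 the list's median was 0.35 above that of the dog's other arrays.

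Matrix genes gave 2 increases among 32 tested, VCAN and HAS2, and 3 adjusted over the list alone. The list did not pass (adjusted p = 0.722), its median was -0.04, its mean 0.03 and its test pointed up. Of 30 immediate early and stretch-responsive genes, KLF4 fell and 29 did not pass (list adjusted p = 0.705). Adjusted over the list alone, 7 rose and 4 fell, with EGR3 at 1.04 and MYC at 1.08. Heat shock and unfolded protein response genes were higher in 18 of 25 (adjusted p = 0.072), with 0 passing over all genes by their brightest probe set and 3 adjusted over the list alone, the chaperones HSPA4 (0.79) and HSPD1 (0.66) having the smallest p. Another probe set of HSPA4 passed over all genes (0.82, limma adjusted p = 0.0434), and 2 of the 3 others had the same sign (lowest -0.03).

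The remaining response lists did not pass, and 0 of their members passed over all genes by their brightest probe set. IL-6/STAT3 and acute phase genes had an adjusted p of 0.456 (TIMP1 0.55, CEBPB 0.33), and hypoxia and glycolysis genes 0.163 (PGAM1 0.51, PFKFB4 0.80). Coagulation and fibrinolysis genes had an adjusted p of 0.722, with 1 of 20 passing adjusted over the list alone, the matrix glycoprotein THBS1 at 1.24, and TFPI at -0.45. Another probe set of THBS1 passed over all genes (1.26, limma adjusted p = 0.0129). That list's median was -0.00, with a mean of 0.09 and a test pointing up. Interferon response genes had an adjusted p of 0.77 (IFI6 0.60, OAS2 -0.22), fluid transport genes 0.705 (the co-transporter SLC12A2 at 0.33, the claudin CLDN18 at -1.35), cholesterol and fatty acid synthesis genes 0.707 (SREBF1 -0.49, INSIG1 -0.39) and cell cycle genes 0.383 (MKI67 -0.29, PLK1 -0.30). CLDN18 was -4.36 lower on the outlying arrays of dog 3 than on its other arrays.

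No list of lung cell markers passed. Alveolar type 2 markers were lower in 10 of 12, with 0 passing and 1 adjusted over the list alone (list adjusted p = 0.0639, and adjusted p = 0.103 with an estimated correlation). The surfactant protein genes SFTPC and SFTPB stood at -0.55 ± 0.16 (SE, 12 arrays per lung, limma adjusted p = 0.22) and -0.13, and ETV5 at -0.28. Alveolar type 1 markers had an adjusted p of 0.373 (CLIC3 -1.18, EMP2 -0.46), with 1 lower adjusted over the list alone, and AGER, another of them, was -3.04 lower on the outlying arrays of dog 3. Smooth muscle and fibroblast markers were lower in 14 of 20 (adjusted p = 0.0639, MYLK -0.67, DCN -0.46), and on the outlying arrays their median was -0.32. Of 22 endothelium markers RAMP2 fell and NOS3 stood at 0.56, with 1 higher and 1 lower adjusted over the list alone and a list adjusted p of 0.705.

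Leukocyte markers showed no shift that passed. Neutrophil markers had an adjusted p of 0.865 (LTF -0.39, S100A8 -0.23), macrophage and monocyte markers 0.641 (MARCO -0.52, FCGR2A 0.38), T and NK cell markers 0.865 (CD3E 0.24, TRBC1 0.21) and B and plasma cell markers 0.707 (BLK 0.25, IGHG1 0.19). Red cell and platelet markers had an adjusted p of 0.538 (HBB -0.51, ITGA2B -0.51), airway epithelium markers 0.937 (TUBA1A -0.34, KRT14 0.45) and pleural mesothelium markers 0.456 (GPM6A -1.04, KRT19 -0.29). Airway cartilage and gland markers had an adjusted p of 0.949 (SOX9 0.43, MATN1 -0.33), with a median of -0.04, a mean of -0.00 and a test pointing up. Over these leukocyte, blood, airway, mesothelium and cartilage lists, 0 members passed over all genes and 1, the mesothelium marker GPM6A, passed adjusted over the list alone.

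At the base nondependent site the same comparison gave the most calls of the 4 sites. HAS2 rose 17.3-fold (log2 change 4.11 ± 0.66, SE, n = 3 dogs, limma adjusted p = 0.00738), from a mean log2 signal of 6.05 ± 1.02 (SD) to 10.16 ± 0.82. MYC, a transcription factor of growth, rose 9.68-fold (3.28 ± 0.60, adjusted p = 0.0124), MT2A 8.73-fold (3.13 ± 0.44, adjusted p = 0.00517), MT1F 6.99-fold and CCT8 6.87-fold (2.78 ± 0.46, adjusted p = 0.00738). HAS2, MYC and CCT8 were each called Present on 2 of 3 control arrays, and the control mean of MYC had an SD of 1.67. Their folds thus rest in part on signals not called Present. The other probe set of CCT8 stood at -0.69. SRGAP3 fell by 2.19 ± 0.43, AAAS, a nuclear pore protein, by 1.41 ± 0.23 (adjusted p = 0.00738), and CCNT1, a cyclin of transcription elongation, by 1.30 ± 0.29. SRGAP3 and AAAS were called Present on 2 of 3 injured arrays. BTBD18 was also called lower (adjusted p = 0.043) but was Present on 1 of 3 injured and 2 of 3 control arrays, so its size is not given. In all, limma called 81 probe sets, 74 higher and 7 lower, and 80 had the same sign in 3 dogs.

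FCMR, an IgM receptor of lymphocytes, was called Present on 0 of 3 injured and 3 of 3 control arrays there. Its bound by detection alone was 2.75-fold lower, the same size as its limma estimate (log2 change -1.46, adjusted p = 0.0499). The limma confidence interval of -2.14 to -0.78 allows a smaller fall than this bound. The other probe set of FCMR stood at 0.04. NAMPT, PRMT1, G3BP1 and TRIB1, named above, rose by 2.76, 2.25, 2.43 and 2.07, with the other probe set of NAMPT at -0.58. The arrays of this site are part of the mean of 4 sites, so the 2 results share arrays. Over the 74 increases, the median log2 change was 1.68 there, 0.60 at the base dependent site, 0.20 at the apex nondependent and 0.08 at the apex dependent site. These probe sets were picked for passing at the base nondependent site, which by itself favours a larger median there. Of the 81 calls, 76, 53 and 49 had the same sign at those sites. Tested directly, the injury effect at this site minus the mean of the other 3 gave 0 calls by limma, with 1631 probe sets at an unadjusted p under 0.05.

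**Figure D1:**
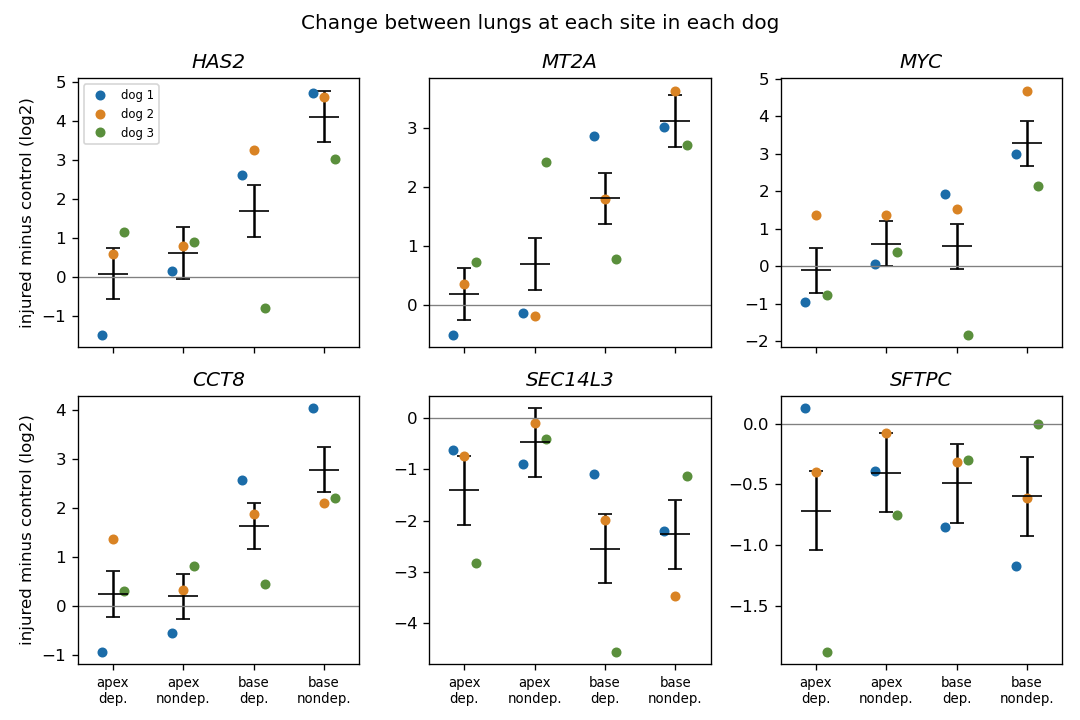
Injured minus control log2 signal (vertical axis) at the 4 sites (horizontal axis) for 6 genes, with a point for each dog, a bar at the mean of 3 dogs and whiskers of 1 SE from limma. HAS2, MT2A, MYC and CCT8 have their highest means at the base nondependent site (4.11, 3.13, 3.28 and 2.78), where each dog lies above 0, while SEC14L3 has means below 0 at each site. HAS2, MT2A, MYC and CCT8 were named among the increases of that site, which by itself favours high means there.

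Of the 21 oxidative stress and metallothionein genes, 7 rose at the base nondependent site, over all genes and adjusted over the list alone (list adjusted p = 1.98e-10, and adjusted p = 0.000106 with an estimated correlation). MT2A, MT1F, MT1H (2.46) and MT1X (2.29) rose most, and the 1 that is no metallothionein, singled out after its value was seen, was the thiol reductase TXN (2.21). Without metallothioneins the list's adjusted p was 0.638. Immediate early genes passed as a list (adjusted p = 0.00117, and adjusted p = 0.0604 with an estimated correlation), with MYC rising, EGR3 at 2.32 (adjusted p = 0.0705), 23 of 30 higher and 5 rising adjusted over the list alone. Heat shock and unfolded protein response genes also passed (adjusted p = 0.00179, and adjusted p = 0.141 with an estimated correlation), with HSPA4 rising by 1.96, HSPD1 at 1.27, and 2 of 25 rising adjusted over the list alone. The surfactant gene SFTPC stood at -0.60 and IL6 at 0.17, and neither passed.

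The 3' minus 5' log2 signal of GAPDH was higher in the injured than the control array of this site by 1.35, 0.41 and 0.09 in dogs 1 to 3, and that of ACTB differed by 1.03, 0.48 and -0.47. With both as covariates limma called 9 probe sets there, and MT2A passed (2.62, adjusted p = 0.0404) while HAS2 (3.18, adjusted p = 0.077) and MYC (2.70, adjusted p = 0.204) did not. The 81 calls came to 43 under quantile normalization, and limma called 0 with no replicate block for the dog, where 1085 had an unadjusted p under 0.05. It called 4 without dog 1, 134 without dog 3 and 0 without dog 2, where 1123 had an unadjusted p under 0.05.

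The other 3 sites had no call. At the base dependent site MT2A and MT1F stood at 1.81 and 1.61, and the oxidative stress and metallothionein list passed (limma cameraPR adjusted p = 0.00857, and adjusted p = 0.402 with an estimated correlation), with 6 of 21 rising adjusted over the list alone and an adjusted p of 0.946 without metallothioneins. Limma called 0 probe sets there, and 1244 had an unadjusted p under 0.05. The smallest limma adjusted p over all probe sets was 0.08. UBA3, of the NEDD8 pathway (1.46), PPRC1, a transcriptional coactivator (1.95), DAPK2, a kinase of cell death (1.26), and SEC14L3 (-2.55) each had an adjusted p of 0.505. RPRD2 and ARHGDIB, both higher in the injured lung, were also among the genes with the smallest p. SEC14L3 was lowest there in dog 3, whose array stood apart.

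At the apex dependent site the immediate early and stretch-responsive list pointed down (adjusted p = 0.00329, and adjusted p = 0.145 with an estimated correlation). KLF4 stood at -1.44 (adjusted p = 0.196) and GADD45B at -0.99, 19 of 30 were lower, 0 passed over all genes and 4 fell adjusted over the list alone. KARS1, a tRNA synthetase (-1.18), had an adjusted p of 0.196. ZNF669 and TNFRSF11A, both higher in the injured lung, and ARHGEF12, lower there, were also among the genes with the smallest p. The smallest limma adjusted p over all probe sets was 0.0911. Limma called 0 probe sets at this site, and 1391 had an unadjusted p under 0.05. The list's adjusted p was 0.079 under quantile normalization. The 3' minus 5' signal differed between the lungs there by -1.10, 0.07 and 0.31 for GAPDH in dogs 1 to 3. For ACTB it differed by -2.04, -0.14 and 0.66. The injured array of dog 3 at this site was among those that stood apart, where the list's median difference from the dog's other arrays was 0.005.

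At the apex nondependent site limma called 0 probe sets, and 1083 had an unadjusted p under 0.05. MPPE1, a phosphoesterase, stood at -2.54 ± 0.47 (SE, n = 3 dogs, limma adjusted p = 0.405), and ZNF451 (1.27) and NDUFV1, of respiratory complex I (-1.51), had an adjusted p of 0.514. None of the 25 lists passed there.

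Whether the injury effect differed between parts of the lung was tested as an interaction. Between base and apex, the injury effect on oxidative stress and metallothionein genes was higher at the base (adjusted p = 0.000312, and adjusted p = 0.0415 with an estimated correlation), with MT2A at 2.03 and MT1F at 1.87, 7 higher and 1 lower adjusted over the list alone and an adjusted p of 0.755 without metallothioneins. That on immediate early genes was higher at the base too (adjusted p = 0.000457, and adjusted p = 0.0415 with an estimated correlation), with site means of -0.26 and 0.11 at the apex and 0.13 and 0.48 at the base, so a fall at the apex dependent site enters it, with MYC at 1.66 and GADD45B at 0.74, 23 of 30 above 0 and 0 passing, adjusted over the list alone as well. T and NK cell markers went the other way (adjusted p = 0.00993, and adjusted p = 0.261 with an estimated correlation), with CD8A at -0.80, GZMK at -1.01, 17 of 21 below 0 and 0 passing, adjusted over the list alone as well. Limma called 0 single probe sets for this interaction, 1654 had an unadjusted p under 0.05, and CNTNAP2 (-2.14) had an adjusted p of 0.157 and AAAS (-1.11) and ZFP36L1 (1.50) of 0.19, where further probe sets of CNTNAP2 and ZFP36L1 had the other sign. The injury difference of 3' minus 5' signals ran the same way in dog 1, from -1.10 and -0.24 (GAPDH) and -2.04 and -1.52 (ACTB) at the apex to 1.42 and 1.35 and 1.26 and 1.03 at the base. For GAPDH it moved little in dog 2 (0.07 and -0.15 to 0.17 and 0.41) and not that way in dog 3 (0.31 and -0.22 to -0.17 and 0.09). For ACTB it was higher at the base in these dogs too, at either position. It went from -0.14 and -0.03 to -0.12 and 0.48 in dog 2, and from 0.66 and -1.19 to 0.90 and -0.47 in dog 3. With these signals as covariates the adjusted p was 0.0134 for oxidative stress and metallothionein genes (adjusted p = 0.353 with an estimated correlation), 0.0519 for immediate early genes and 0.406 for T and NK cell markers. Without the 3 outlying arrays of dog 3 limma called 24, and 32 without dog 3.

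**Figure D2:**
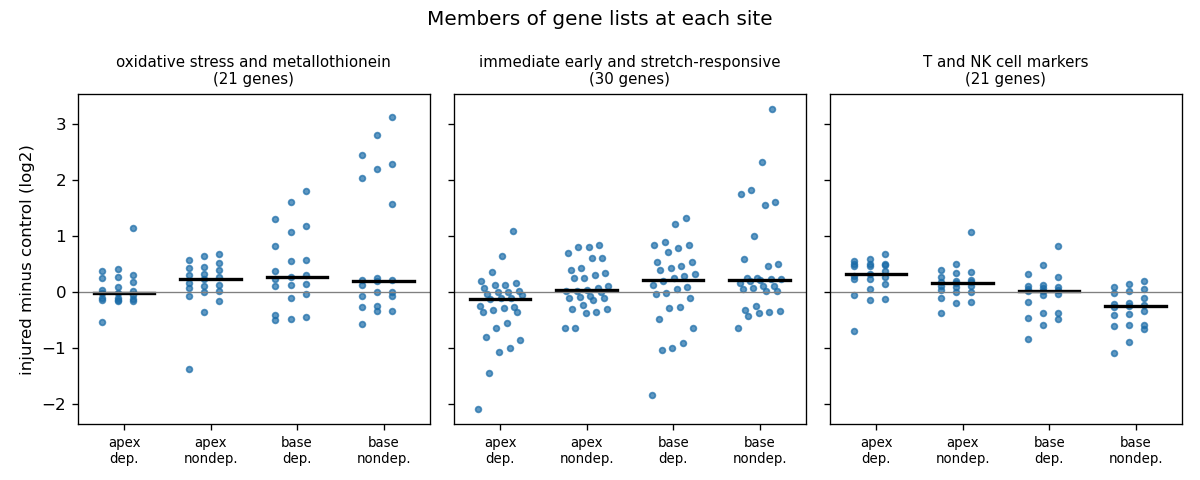
Injured minus control log2 change (vertical axis) of each tested member of 3 gene lists at the 4 sites (horizontal axis), with a point for each gene and a bar at the list's median. The medians of T and NK cell markers run from 0.32 at the apex dependent site to -0.24 at the base nondependent site, and those of immediate early genes from -0.12 to 0.22.

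Between dependent and nondependent parts, the injury effect on immediate early genes was lower in dependent parts (adjusted p = 0.00272, and adjusted p = 0.131 with an estimated correlation), with KLF2 at -0.95 and NR4A2 at -1.67, 20 of 30 below 0 and 0 passing, adjusted over the list alone as well. Oxidative stress and metallothionein genes pointed the same way (adjusted p = 0.0353, and adjusted p = 0.559 with an estimated correlation), with 15 of 21 below 0, although GCLM, an enzyme of glutathione synthesis, stood at 1.81 and passed adjusted over the list alone. Limma called 0 probe sets, 1088 had an unadjusted p under 0.05, and CCT7 (-1.38), IMPA2 (1.99), TANC2 (2.20) and STAP1 (1.62) had an adjusted p of 0.851. The adjusted p of these lists was 0.103 and 0.622 under quantile normalization, and 0.00636 and 0.124 with the 3' minus 5' covariates.

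Within the injured lung, base and apex were compared across positions. HAS2 was 6.82-fold higher at the base (log2 difference 2.77 ± 0.47, SE, 6 arrays per level from 3 dogs, limma adjusted p = 0.0301), MT2A 3.94-fold (1.98 ± 0.31, adjusted p = 0.0291), MT1F 3.51-fold (1.81 ± 0.29), MT1E 2.34-fold (1.23 ± 0.20) and EMP1, a membrane protein of epithelium, 2.67-fold (1.42 ± 0.25, adjusted p = 0.0444). EMP1 had 1 of 2 further probe sets with the same sign. HAS2 and EMP1 were called Present on 4 and 5 of the 6 apex arrays. These were 5 of 7 calls, all higher at the base and with the same sign in 3 dogs. Oxidative stress and metallothionein genes passed as a list (adjusted p = 4.6e-07, and adjusted p = 0.00388 with an estimated correlation), with 3 of 21 rising, 7 rising and 1 falling adjusted over the list alone, and an adjusted p of 0.793 without metallothioneins. Immediate early genes passed (adjusted p = 0.000663, and adjusted p = 0.0444 with an estimated correlation), with GADD45B at 0.73, GADD45A at 1.26 and 3 rising adjusted over the list alone. Heat shock and unfolded protein response genes passed too (adjusted p = 0.0147, and adjusted p = 0.234 with an estimated correlation), with HSPA4 at 1.08, rising adjusted over the list alone, and CHAC1 at -0.68.

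The 3' minus 5' signal of GAPDH in the injured lung went from 1.33 and 2.09 at the apex to 3.08 and 3.01 at the base in dog 1, from 1.39 and 1.77 to 1.73 and 1.88 in dog 2, and from 2.01 and 1.36 to 1.55 and 1.51 in dog 3. That of ACTB went from -1.76 and -0.78 to -0.24 and -0.52 in dog 1. In dog 2 it went from -1.43 and -1.48 to -1.06 and -0.86, and in dog 3 from 0.13 and -1.39 to 0.19 and -1.81. HAS2 differed by 4.33, 3.42 and 0.56 and MT2A by 3.06, 2.15 and 0.72 in dogs 1 to 3. With the 3' minus 5' covariates limma called 0 (1473 at an unadjusted p under 0.05), HAS2 stood at 2.09 (adjusted p = 0.258) and MT2A at 1.61 (adjusted p = 0.221), and the adjusted p of the lists was 8.96e-05 for oxidative stress and metallothionein, 0.0288 for immediate early genes (adjusted p = 0.245 with an estimated correlation) and 0.251 for heat shock genes. The 7 calls were 23 under median centring and 59 without the outlying arrays of dog 3, while limma called 0 under quantile normalization, where 1620 had an unadjusted p under 0.05, and 0 with no replicate block and on dog means paired by dog, where 1123 and 1380 did. It called 0 without dog 1 and without dog 2, with 1368 and 1435 at an unadjusted p under 0.05, and 102 without dog 3. The injured base nondependent arrays also enter the comparison of that site, so the 2 results share arrays.

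Dependent and nondependent parts of the injured lung differed in immediate early genes as a list, lower in dependent parts (adjusted p = 0.00467, and adjusted p = 0.158 with an estimated correlation), with KLF4 at -0.76, NR4A2 at -1.35, 19 of 30 lower and 4 falling adjusted over the list alone. GCLM (1.55), PLCB3, a phospholipase C (1.06), EMP1 (-1.08) and SOX4, a transcription factor (-0.72), had an adjusted p of 0.918. Limma called 0 probe sets, and 1056 had an unadjusted p under 0.05. The list's adjusted p was 0.0668 under quantile normalization.

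Position and level within the control lung give the background against which the injured lung is set. Dependent parts had higher oxidative stress and metallothionein genes as a list (adjusted p = 0.00378, and adjusted p = 0.19 with an estimated correlation), with 16 of 21 higher, MT2A at 0.81 and MT1H at 0.62, 0 passing adjusted over the list alone and an adjusted p of 0.348 without metallothioneins. PACSIN3 (1.13, adjusted p = 0.347), ODAD2, of motile cilia (-1.22, adjusted p = 0.99), and ITM2C (0.97) did not pass, and limma called 0 probe sets, with 959 at an unadjusted p under 0.05. Between base and apex of the control lung no list passed. CSPG5 (-1.09), GPATCH8 (0.71) and CNTNAP2 (1.10) had an adjusted p of 0.945, and limma called 0 probe sets, with 1033 at an unadjusted p under 0.05.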

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

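The tests of between-array normalization, of RNA quality at the base nondependent site and of the counts without dog 3, the simulation and the list tests of that site against the others, the hemoglobin probe sets used for blood, the intervals required for blood and neutrophils, and the analyses without the 3 outlying arrays or without metallothioneins were chosen only after the result was seen. The list results below stand out because they passed a test of the difference in injury effect between parts of the lung, at the preset correlation between genes. Not all of them passed with an estimated correlation. By level, the oxidative stress list did not pass without its metallothioneins, as given above.

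By level, base against apex, the injury effect on oxidative stress and metallothionein genes had an adjusted p of 0.000312, with site means of 0.08, 0.16, 0.41 and 0.75 at the apex dependent, apex nondependent, base dependent and base nondependent sites. For immediate early genes the adjusted p was 0.000457, with site means of -0.26, 0.11, 0.13 and 0.48. T and NK cell markers had an adjusted p of 0.00993, with site means of 0.28, 0.17, -0.04 and -0.30, and adjusted p = 0.261 with an estimated correlation. By position, dependent against nondependent, immediate early genes had an adjusted p of 0.00272, and adjusted p = 0.131 with an estimated correlation. Oxidative stress and metallothionein genes had an adjusted p of 0.0353 by position, and adjusted p = 0.559 with an estimated correlation. Without the 3 outlying arrays of dog 3 the adjusted p of these 5 results, in the order given, was 7.13e-08, 0.000234, 0.0265, 0.000242 and 0.0289. With the 3' minus 5' covariates it was 0.0134, 0.0519, 0.406, 0.00636 and 0.124, and for the first 2 adjusted p = 0.353 each with an estimated correlation, against 0.0415 each without the covariates.

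The first pattern weighed is that 81 probe sets passed at the base nondependent site and 0 at each of the others. Between-array normalization as the whole cause is argued against by 43 calls there under quantile normalization and 118 under median centring, and outlying arrays of dog 3 that hid changes elsewhere by the counts without dog 3, at most 3 at the other sites and 134 there, although in dogs 1 and 2 the 100 genes that rose most there in dog 3 had medians of 0.431, 0.248 and 0.113 at the base dependent, apex dependent and apex nondependent sites and 0.042 there, which leaves the ratio planned for it, 6.472 (-6.937 to 24.502), with a denominator near 0 and undecided. RNA quality stays open: with the 3' minus 5' signals as covariates 9 of the 81 passed, 81 kept their sign, and the median of the 74 increases was 1.49 (SE 0.34) in place of 1.68 (SE 0.32). A larger injury effect at this site stays open too, since its difference from the mean of the other 3 sites gave 0 calls by limma (1631 at an unadjusted p under 0.05), which had been set beforehand as arguing against it, while the oxidative stress and the immediate early lists passed that test (adjusted p = 0.029 each with an estimated correlation, but 0.121 each with the 3' minus 5' covariates). That bound was too strict. In simulated data with independent noise the test recovered 61 of 100 differences of log2 2 but 12 of 100 of log2 1. For such noise 0 calls speaks against many differences of log2 2 and not against smaller ones. In the oxidative stress list 13 of 21 members were higher by that test, with a median difference of 0.11. That list was not run without metallothioneins there.

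The second pattern is that 3 arrays of the injured lung of dog 3 stood apart. They were compared with the dog's other 5 arrays, which are its control-lung arrays and its injured base nondependent array. The difference between the lungs therefore enters each value below. More blood in those pieces than in the other 5 is argued against by hemoglobin alone: 9 of 9 hemoglobin probe sets were lower there (median -1.29). Red cell and platelet markers together had a median difference of 0.034 (bootstrap interval -0.295 to 0.535), an interval too wide to decide by itself. RNA degradation stays open, because the 3' minus 5' difference rose by 0.404 on average but by -0.033 for GAPDH and 0.842 for ACTB. An influx of inflammatory cells stays open too, with a median difference of neutrophil markers of 0.198 (0.021 to 0.337), 16 of 22 higher, beside a median of 0.11 over all genes. The arrays also belong to 1 lung of 1 dog, so a response of that animal and a technical fault cannot be told apart.

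The third pattern is that metallothionein probe sets rose together. Over the 24 arrays the residuals of the 11 probe sets had a median pairwise correlation of 0.733, against at most 0.244 in 1000 random sets. This is consistent with probe sets of several human paralogs reading the transcripts of fewer dog genes. Shared regulation of those genes was not tested, and the number of metallothionein calls says little about how many dog genes rose.

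Other splits of the arrays within dogs were counted for each comparison. For the mean of 4 sites, with sites exchanged within dogs, 3 of 100 splits, the real one included, gave as many as the 42 calls. That share is under 0.05, so the count was uncommon among these splits, but chance is not excluded. Even this reading holds only if the pieces of a lung count as separate units. The lavage was given to whole lungs, which these splits do not follow. The highest other split gave 99, more than the real one, and what that split follows was not tested. With whole lungs exchanged there are 4 splits, too few for a share under 0.05, and the real value was 42 (1 split as large) and the highest other 0. The same holds for the single sites: real 81 and highest other 0 at the base nondependent site (1 of 4), and real 0 and highest other 0 at the other 3 sites (4 of 4). For base minus apex in the injured lung 2 of 32 splits gave as many as the 7 calls, the highest other 12, so chance cannot be excluded. For the 2 interactions, for dependent minus nondependent in the injured lung and for both contrasts in the control lung the real value was 0, which 32 of 32 splits reach, with a highest other of 0, except 1 for dependent minus nondependent in the control lung.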

How the results depend on the processing

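The analyses without the 3 outlying arrays of dog 3, with 3' minus 5' covariates and of the oxidative stress list without metallothioneins were added only after the result was seen. Counts by limma moved by over 1.5 times as follows, and the cause was not tested unless the setting drops arrays, averages pieces or loosens the limit. For the mean of 4 sites (42) there were 6 with no replicate block, 6 on dog means and 93 at an adjusted p under 0.10, and 0 to 26 without each dog in turn. At the apex dependent site (0) there was 1 at an adjusted p under 0.10. At the base dependent site (0) there were 1 with no detection filter, 2 with array weights, 1 at an adjusted p under 0.10, and 0 to 3 without each dog in turn. At the base nondependent site (81) there were 43 under quantile normalization, 0 with no replicate block (1085 at an unadjusted p under 0.05), 159 with array weights, 151 without the outlying arrays, of which 80 were among the 81, 155 at an adjusted p under 0.10, 9 with 3' minus 5' covariates, and 0 to 134 without each dog in turn. For the interaction with level (0) there were 24 without the outlying arrays, 2 at an adjusted p under 0.10, and 0 to 32 without each dog in turn. For base minus apex in the injured lung (7) there were 0 under quantile normalization (1620 at an unadjusted p under 0.05), 23 under median centring, 23 with an offset of 50, 0 with no replicate block (1123), 116 with array weights, 0 on dog means (1380), 59 without the outlying arrays, 45 at an adjusted p under 0.10, 0 with 3' minus 5' covariates (1473), and 0 to 102 without each dog in turn.

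For the mean of 4 sites the other settings gave 29 to 60 calls, and 19 of the 42 were shared without the outlying arrays and 21 with 3' minus 5' covariates. Without each dog in turn, the 42 and the 81 probe sets kept their sign. For the 42 and for 80 of the 81 this could not fail, as they had the same sign in 3 dogs. Genes named as passing were picked for the same sign too, so leaving out a dog could not reverse them. Of 508 alternative values of the 37 results of named genes that passed, 299 stayed past the threshold, 209 did not and 0 reversed. Those that did not were 37 without dog 2, 35 with no block, 34 without dog 1, 23 on dog means, 23 with 3' minus 5' covariates, 18 without dog 3, 11 under quantile normalization, 10 without the outlying arrays, 9 with no detection filter, 5 under median centring, 2 with an offset of 50 and 2 with a filter of 3 Present arrays. Dog means were not run at single sites, so the 81 calls were not tried on them. Of the named results that were, 4 stayed past the threshold. Of the list results 215 kept their side of the threshold and 62 lost it. The dog block by itself equals the model used, the deposited table holds the same values, and no batch was recorded, so these were not run separately. Signal over background limits the tests: 2052 probe sets were Present on no array and 5448 on all 24.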

Other observations

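The families here were picked by their symbols only after the result was seen, and their tests were chosen only then. At the base nondependent site, subunits of the cytosolic chaperonin CCT, which folds actin and tubulin, were higher in the injured lung in 7 of 7, with a median of 1.20 (limma cameraPR adjusted p = 4.23e-07 with an estimated correlation) and 3 passing. Their medians were 1.59, 1.08 and 1.10 in dogs 1 to 3. Translation initiation factors of the EIF symbols were higher in 33 of 42, with a median of 0.35 (adjusted p = 0.000161) and 5 passing, and hnRNP and SR proteins of RNA splicing in 25 of 28, with a median of 0.47 (adjusted p = 0.0166) and 2 passing. Importins and exportins, which carry proteins and RNA through nuclear pores, were higher in 11 of 18, with a median of 0.15 (adjusted p = 0.00625) and 2 passing. These families were picked through the members that passed, and without those members the adjusted p was 0.0025 for CCT, 0.00595 for EIF, 0.0556 for hnRNP and SR proteins and 0.0941 for importins and exportins. The 3' minus 5' signal of GAPDH was also higher in the injured lung there, by 1.35, 0.41 and 0.09 in dogs 1 to 3, and with the 3' minus 5' covariates the medians over all members were 0.87 (adjusted p = 1.36e-06), 0.40 (0.00165), 0.25 (0.08) and 0.27 (0.013) in the same order. Under quantile normalization the medians were 1.30 for CCT, 0.27 for EIF, 0.33 for hnRNP and SR proteins and 0.19 for importins and exportins.

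The family of ribosomal protein genes left out RPL36AL, which passed at that site (1.26, limma adjusted p = 0.039). It also left out probe sets with several symbols, some of which passed there. The ribosomal protein genes in it were higher there in 52 of 53, with a median of 0.49 (adjusted p = 0.000789) and 0 passing. Scaling moved them: 0.13 under quantile normalization, with 39 of 53 higher, and 0.59 under median centring. These scalings moved all probe sets there by 0.085 and 0.1. At the apex dependent site the same genes were lower, with a median of -0.37 (adjusted p = 0.0336), -0.14 under quantile normalization and -0.47 under median centring, where quantile normalization moved all probe sets by -0.101. The injury effect on them differed by level (adjusted p = 0.00234, median 0.48). With the 3' minus 5' covariates the adjusted p of ribosomal protein genes was 0.00513 at the base nondependent site, 0.0693 at the apex dependent site and 0.0247 by level. The 41 EIF and CCT members that did not pass had a median of 0.292 at the base nondependent site (adjusted p = 0.0025). A coordinated rise of genes of protein synthesis and folding there may therefore reach beyond the genes that passed, a hypothesis found and tested on the same data.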
